A study of Homo sapiens with 28 samples.

How the data were processed

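FOXA1 ChIP-seq was analysed in 24 ChIP samples and 4 input samples of the human breast cancer cell lines MCF-7 and ZR75-1. The ChIP samples formed 8 groups of 3, by cell line, antibody (ab5089 or ab23738) and treatment (10 nM estrogen or ethanol vehicle for 45 min after 3 days without hormone). The files used were 8 peak lists, each tied by the labels to all 3 samples of a group. Bowtie2 2.2.6, MACS2 2.0.10.20131216 and DiffBind are named per the submitters' processing notes, which give the builds hg38 and GRCh38. How the replicates were combined before calling is not given in the sources used here. Replicate spread could not be had, since the lists carry no replicate. The input samples had no list of their own and were not used here.

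Each peak has a start, an end, a summit offset in bp, a fold enrichment over background (a linear ratio made by the authors' peak caller), and a −log10 p-value and a −log10 q-value, as deposited by the authors. The lists hold peaks with a −log10 q from 2.00 upwards and widths from 200 bp. Fold enrichment, p and q are the caller's own values for a peak within its list, so they move with the depth and the input of that list.

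Chromosomes 1 to 22 and X were used. Shares of peaks with an overlapping peak (at least 1 bp) were given with 95% Wilson intervals, and no test was run between treatments because each condition has 1 list. Peaks of the 4 lists of a line, or of all 8 lists, that shared at least 1 bp were merged into regions. A region was estrogen-only or vehicle-only when both antibodies called it with that treatment and neither called it with the other. The number expected for independent lists was n1 × n2 / N, with N the regions called by both antibodies in at least 1 treatment. It was also summed over 10 strata of the mean percentile rank of fold enrichment. A region was line-specific when all 4 lists of a line and none of the other called it.

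Genes came from a table of 19974 protein-coding genes of GRCh38, the build of the lists. The table gives the span of each gene without strand or exons. Distances were therefore measured to the gene span and to its ends, in place of the transcription start site, and promoters, exons and introns were not analysed here. Motifs were not analysed here, since no genome sequence was used. All 125 members of the 8 gene lists were found, WISP2 under the symbol CCN5. The lists hold estrogen-induced, estrogen-repressed, luminal identity, basal and mesenchymal, liver, prostate androgen-response, blood cell and housekeeping genes. The number of members with a region within 50 kb was compared with 10000 random lists, matched gene by gene on 20 bins of the number of regions within 50 kb. The percentile is the share of random lists with fewer genes, and describes these lists of peaks only.

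The reads at each summit (t) and the local background (b) were solved from the deposited fold, taken as (t + 1) / (b + 1), and from the deposited −log10 p, taken as the Poisson chance of more than t reads. Peaks whose −log10 p was not met within 0.001 were left out of read values. The lowest background of a list stands for its depth. For the comparison of reads in the closing part, regions with 1 peak in each of the 4 lists of a line were used, log2 ratios of estrogen to vehicle were centred on their median per antibody, and a region counted as higher or lower when it passed 1.5-fold with both antibodies. These reads set values of different lists side by side and have no replicate check.

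The named genes and regions followed a rule fixed before the data were examined. It covers 11 estrogen targets and regulators, up to 6 members of each list and direction, and per line the 10 estrogen-only and 5 vehicle-only regions with the highest mean percentile rank of fold enrichment. It also covers the 10 leading line-specific regions of each line and the 10 leading regions of all 8 lists. Regions named for their reads, and examples of regions shared between lines, were chosen after their values were seen.

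The alternatives were a −log10 q of 5 or more, summits within 100 bp, overlap of at least 50% of both peaks, equal numbers of the strongest peaks by −log10 p, all contigs, the strongest 5% of peaks or the strongest 10% by −log10 q, absence within 1 kb, a distance of 5 kb to a gene end, windows of 10 and 100 kb, and regions called by ab23738 alone. For the reads they were scaling by background, the strongest peak where a list had several, regions with fewer than 200 reads, and a limit of 2-fold with either scaling.

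On simulated data, reads were recovered exactly for 100% of 20000 peaks, and overlap calls differed from a brute-force count in 0 of 12000 cases. Of 200 gene lists without enrichment, 1.5% exceeded the 97.5th percentile. Of 200 regions raised by a factor of 2 among 48835 regions of MCF-7, 97% were called higher, and 96.5% among 42909 regions of ZR75-1. For a factor of 1.5 these shares were 26.5% and 31%, and for a factor of 3 they were 100% in both lines. The shares for raised regions cover counting error only and not the spread between ChIP preparations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.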

Results

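FOXA1 is a forkhead transcription factor that opens chromatin ahead of the estrogen receptor. Its binding was measured by ChIP-seq in MCF-7 and ZR75-1, both breast cancer cell lines that express the estrogen receptor. The cells were deprived of hormone for 3 days and then given 10 nM estrogen or ethanol vehicle for 45 min. FOXA1 was precipitated with 2 antibodies, ab5089 and ab23738. Each combination of cell line, antibody and treatment comprised 3 ChIP samples, 24 in all, and each of the 4 combinations of line and treatment had 1 input sample. The data analysed were 8 peak lists, 1 per combination. Because the replicates of a group share 1 list, no spread between replicates was available, and no p-value was computed between treatments. The intervals given are 95% Wilson intervals and cover the counting of peaks only.

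With ab5089, 66052 peaks were listed for vehicle and 64050 for estrogen in MCF-7, against 60175 and 51307 in ZR75-1. With ab23738, the lists held 133202 and 119080 peaks in MCF-7 and 124044 and 121747 in ZR75-1. The vehicle list was the longer in 4 of 4 pairs. Median peak widths lay between 338 and 374 bp. The lists state no depth, so the reads piled up at each summit and the local background were solved from each peak's fold enrichment and p-value. A whole number of reads was found for 739650 of 739657 peaks, within a tolerance of 0.001 on the −log10 p. The lowest background per list, which scales with depth, ranged from 6.37 reads in MCF-7 ab23738 estrogen to 8.82 reads in ZR75-1 ab5089 vehicle. For vehicle and estrogen it was 7.56 and 7.20 with ab5089 and 7.66 and 6.37 with ab23738 in MCF-7. In ZR75-1 it was 8.82 and 6.89 with ab5089, and 7.43 and 8.47 with ab23738. Vehicle thus had the higher background except in ZR75-1 with ab23738. Whether depth accounts for the longer vehicle lists was not tested. The peaks carried a median of 44 to 65 reads at the summit. The values stopped at 400 reads in every list whatever its depth, so 400 is a ceiling of the values and not a measured maximum.

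**Figure D1:**
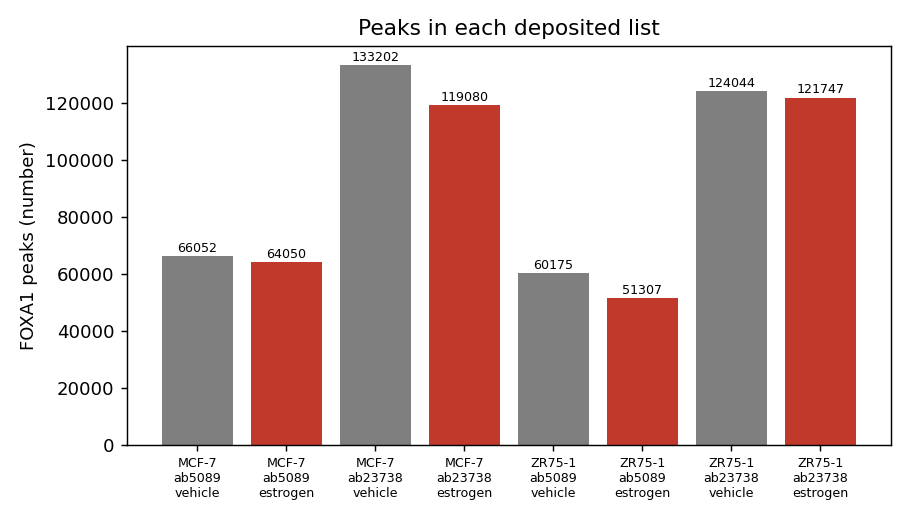
Number of FOXA1 peaks (y axis) in each of the 8 lists, by cell line, antibody and treatment (x axis; grey, vehicle; red, estrogen). The ab23738 lists hold 119080 to 133202 peaks and the ab5089 lists 51307 to 66052.

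The series asks whether FOXA1 binding depends on hormone. Most FOXA1 peaks were called in both treatments. Within 50 kb of ESR1, the estrogen receptor gene, 47 of 91 regions in MCF-7 and 22 of 60 in ZR75-1 were called in all 4 lists of the line, and 1 in each line was called with estrogen only by both antibodies. Near GREB1, an early estrogen target, 20 of 39 regions in MCF-7 and 9 of 34 in ZR75-1 were called in all 4 lists, and 0 and 2 with estrogen only by both antibodies. In MCF-7, 81.9% of estrogen peaks overlapped a vehicle peak with ab5089 (interval 81.6 to 82.2) and 84.4% with ab23738 (84.2 to 84.6). In ZR75-1 the shares were 89.4% (89.2 to 89.7) and 83.2% (83.0 to 83.4). Over the 4 comparisons together, 84.3% of estrogen peaks overlapped a vehicle peak and 78.3% of vehicle peaks overlapped an estrogen peak. The estrogen share was the higher in 4 of 4 comparisons, for which an exact two-sided sign test cannot give a p below 0.13. When each pair of lists was limited to equal numbers of peaks, the shares became 81.7% and 81.6%, and the estrogen share was higher in 3 of 4 comparisons. Lists of equal length give near-equal shares by construction, with differences here of −0.15 to 0.60 percentage points.

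Peaks called in 1 treatment were mostly weak ones, and peaks near the calling threshold are the easiest to miss in 1 list. Fold enrichment per peak is the value of the authors' peak caller. In these comparisons it describes, ranks and filters peaks within a list, and values of different lists stand side by side without being compared. Among the 10% of peaks with the lowest fold enrichment, 36.6% of estrogen peaks and 48.2% of vehicle peaks had no peak of the other treatment. Among the strongest 10%, these shares were 0.0842% (30 of 35619 peaks) and 0% (0 of 38348, with an upper bound of 0.010%). Of the 30 strong estrogen peaks, 29 came from MCF-7 with ab5089, where they made up 0.453% of the strongest 6405 peaks (0.315 to 0.649). All 29 had an estrogen peak with ab23738 as well, and 25 of them also had a vehicle peak with that antibody. The remaining strong peak came from ZR75-1 with ab5089, and ab23738 called it in both treatments.

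**Figure D2:**
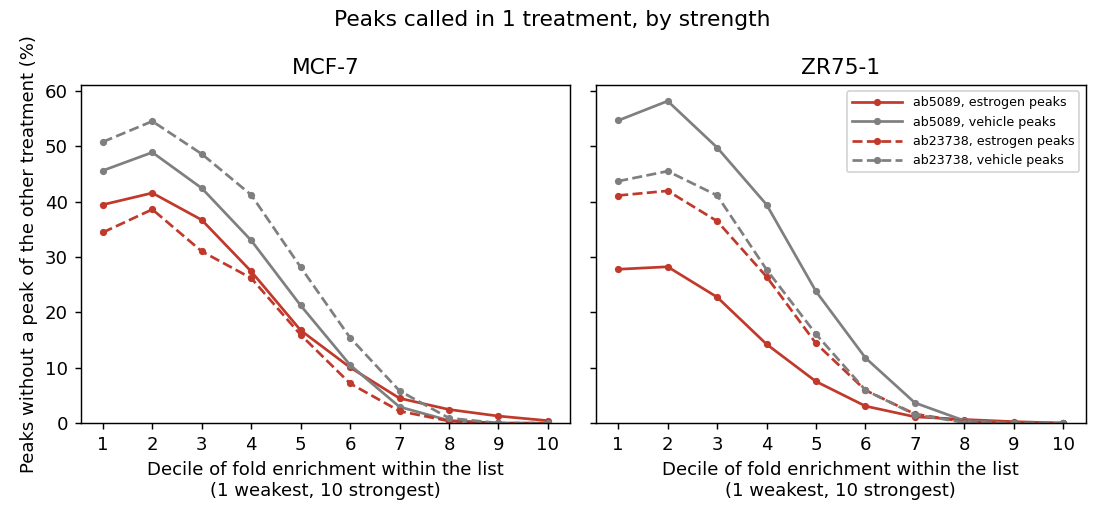
Share of peaks without a peak of the other treatment (y axis, percent) by decile of fold enrichment within each list (x axis, 1 weakest to 10 strongest), for MCF-7 and ZR75-1. Red lines are estrogen peaks and grey lines vehicle peaks, solid for ab5089 and dashed for ab23738; the strongest decile lies between 0% and 0.453%.

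Regions called in 1 treatment by both antibodies were few but more numerous than independent lists give. Peaks of the 4 lists of a line were merged into 151940 regions in MCF-7 and 143524 in ZR75-1, of which 51326 and 45069 were called in all 4 lists. In MCF-7, 1484 regions were called with estrogen and not vehicle by both antibodies, against 245 expected for independent lists and 484 when regions were matched on strength. In ZR75-1 there were 508, against 52.0 and 119. Vehicle-only regions numbered 2264 in MCF-7 (486 and 984 expected) and 955 in ZR75-1 (218 and 487 expected). Regions called with estrogen only by ab5089 and with vehicle only by ab23738 numbered 405 in MCF-7 (399 expected) and 29 in ZR75-1 (81.1 expected). The antibodies shared the input sample of a treatment, so part of the excess may come from it. The larger number of vehicle-only regions was not found with lists of equal length. Such lists give near-equal numbers largely by construction. They cannot show whether the larger number came from longer vehicle lists. With equal numbers of peaks in every list, 3042 estrogen-only and 3012 vehicle-only regions were found in MCF-7, and 2197 and 2111 in ZR75-1.

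The strongest estrogen-only regions lay near CASP7, ARF6 and THADA. In MCF-7 the region with the highest mean rank (chromosome 10, 113678500 to 113679171, GRCh38) ended 23 bp from the span of CASP7, an executioner caspase. Its fold enrichment was 13.8 with ab5089 and 10.3 with ab23738. A region on chromosome 14 (49992701 to 49993369), between genes and 95647 bp from the small GTPase gene ARF6, reached 25.8 and 7.87. It was estrogen-only in ZR75-1 too (49992823 to 49993326), with 10.1 and 7.38. The other 8 of the 10 leading MCF-7 regions lay nearest to JARID2, PLET1, OPA1, FARP1, ENTREP1, CIMIP5, MBOAT1 and SLC47A1. Those in FARP1, ENTREP1, MBOAT1 and SLC47A1 were within the gene span. In ZR75-1 the leading region lay within THADA (chromosome 2, 43273590 to 43274134), with fold enrichments of 7.24 and 12.8. It was followed by ARF6 and by regions nearest to GPR37L1, NEDD1, TFPI2, AP3S2, USP25, SPINK4, PMP22 and GSDMC. The leading vehicle-only regions were nearest to CDC42EP3, DGKB, LRP1B, TLR5 and FBXO28 in MCF-7 and to GABRG2, PIP4K2A, LRFN5, PPP2R2B and MCTP2 in ZR75-1. The vehicle-only region near CDC42EP3 (chromosome 2, 37795889 to 37796779) reached 6.07 and 7.50.

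Between the lines, 49 estrogen-only regions of MCF-7 overlapped an estrogen-only region of ZR75-1. Among the 40711 regions called by both antibodies in both lines, 365 of MCF-7 and 240 of ZR75-1 were estrogen-only, which gives 2.15 expected for independent lists. For vehicle-only regions, 14 were shared against 3.22 expected. These expected numbers between lines were not matched on strength. Within MCF-7, such matching raised the number of estrogen-only regions expected from 245 to 484, so the excess between lines may be overstated. Besides ARF6, the shared estrogen-only regions included 1 near XBP1 (chromosome 22, 28823754 to 28824208 in MCF-7), 23185 bp from the gene. XBP1 encodes a transcription factor of the unfolded protein response and is induced by estrogen.

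Estrogen-induced genes had estrogen-only regions nearby more often than matched random genes. In MCF-7, 10 of 30 genes of this list had an estrogen-only region of both antibodies within 50 kb, more than in 99.5% of 10000 random lists matched on the number of FOXA1 regions (mean 4.14). In ZR75-1 it was 6 of 30, more than in 99.7% (mean 1.48). The 6 with the highest fold enrichment in MCF-7 were PGR, XBP1, CCN5, ABCA3, MYB and TFF1, and those in ZR75-1 were MYB, RET, XBP1, KRT13, GREB1 and CTSD. PGR, the progesterone receptor gene, had 2 such regions in MCF-7, the stronger at chromosome 11, 100981015 to 100981448 (fold enrichment 5.24 and 5.43). Near MYB in ZR75-1, the region at chromosome 6, 135146660 to 135147029 reached 5.57 and 7.71. Vehicle-only regions lay near 4 of the 30 genes in MCF-7 (MYB, KRT13, RARA and GREB1; mean of random lists 5.92) and near 1, ADCY9, in ZR75-1 (mean 2.29). In ZR75-1 the count fell to 3 of 30 within 10 kb, more than in 95.3% of random lists. When a region called by ab23738 alone sufficed, 26 of 30 genes in MCF-7 and 24 of 30 in ZR75-1 had an estrogen-only region, more than in 93.8% and 32.8% of random lists. The random lists then had means of 22.3 and 24.3, and 55.3% and 62.7% of all genes had such a region. The central 95% of random lists ended at 26 of 30 genes in MCF-7 and 28 of 30 in ZR75-1. A list could therefore still stand apart in this setting, and the estrogen-induced list did not lie above that range in either line.

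Of the other 7 lists, 2 lay above the central 95% of random lists in 1 line each. Of 20 luminal identity genes, 8 had an estrogen-only region in MCF-7 (99.2%), led by AGR3, GRHL2, CDH1, ESR1, MUC1 and KRT19, and 3 in ZR75-1 (ESR1, MLPH and KRT19; 84.6%). Of 20 basal and mesenchymal genes, 4 had one in MCF-7 (FOXC1, CDH3, LAMC2 and TP63; 85.2%) and 4 in ZR75-1 (LAMC2, VIM, KRT14 and TP63; 99.2%). Within 10 kb, luminal genes in MCF-7 no longer stood apart (3 of 20, 76.5%). Neither call held when ab23738 alone sufficed, with 17 of 20 luminal genes in MCF-7 (49.9%, mean of random lists 16.4). Basal and mesenchymal genes in ZR75-1 had 14 of 20 (32.1%, mean 14.3). The central 95% of random lists ended at 19 of 20 for luminal genes in MCF-7. For basal and mesenchymal genes in ZR75-1 it ended at 18 of 20. Either list could therefore still have stood apart in this setting. CDH1 and CDH3 are neighbours and shared their region, as did KRT13 and KRT19, which shared theirs with KRT14 in ZR75-1. Of the 15 liver genes, 1 in MCF-7 and 2 in ZR75-1 had an estrogen-only region, namely SERPINA1 in both lines and AMBP in ZR75-1 (91.7% in ZR75-1, and 98.8% within 10 kb). Of the 15 housekeeping genes, TUBB was the 1 with such a region in MCF-7, and 0 had one in ZR75-1. None of the 5 estrogen-repressed, 10 prostate androgen-response or 10 blood cell genes had an estrogen-only region in either line. For vehicle-only regions at 50 kb, no list lay above the central 95% of random lists. The nearest was the estrogen-repressed list in ZR75-1, with CCNG2 and IL1R1 (2 of 5 genes, more than in 95.7%, and in 98.4% within 10 kb), and it had 0 of 5 in MCF-7. Luminal genes with vehicle-only regions numbered 7 in MCF-7, including SPDEF, KRT19, AGR2, AGR3, CLDN4 and TFAP2C, and 4 in ZR75-1, including FOXA1, ESR1 and KRT8. The counts in MCF-7 and ZR75-1 were 4 and 1 for basal and mesenchymal genes, led by CAV1 and SNAI2. They were 2 and 1 for liver genes (ALB and TTR; AHSG), and 2 and 0 for prostate genes (ACP3 and TMPRSS2). Blood cell genes gave 1 and 0 (CD3E) and housekeeping genes 1 and 1 (UBC; PGK1). For regions of both antibodies, 32 such percentiles were computed at 50 kb. Another 32 were computed for each alternative, namely 10 kb, 100 kb, and ab23738 alone sufficing.

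**Figure D3:**
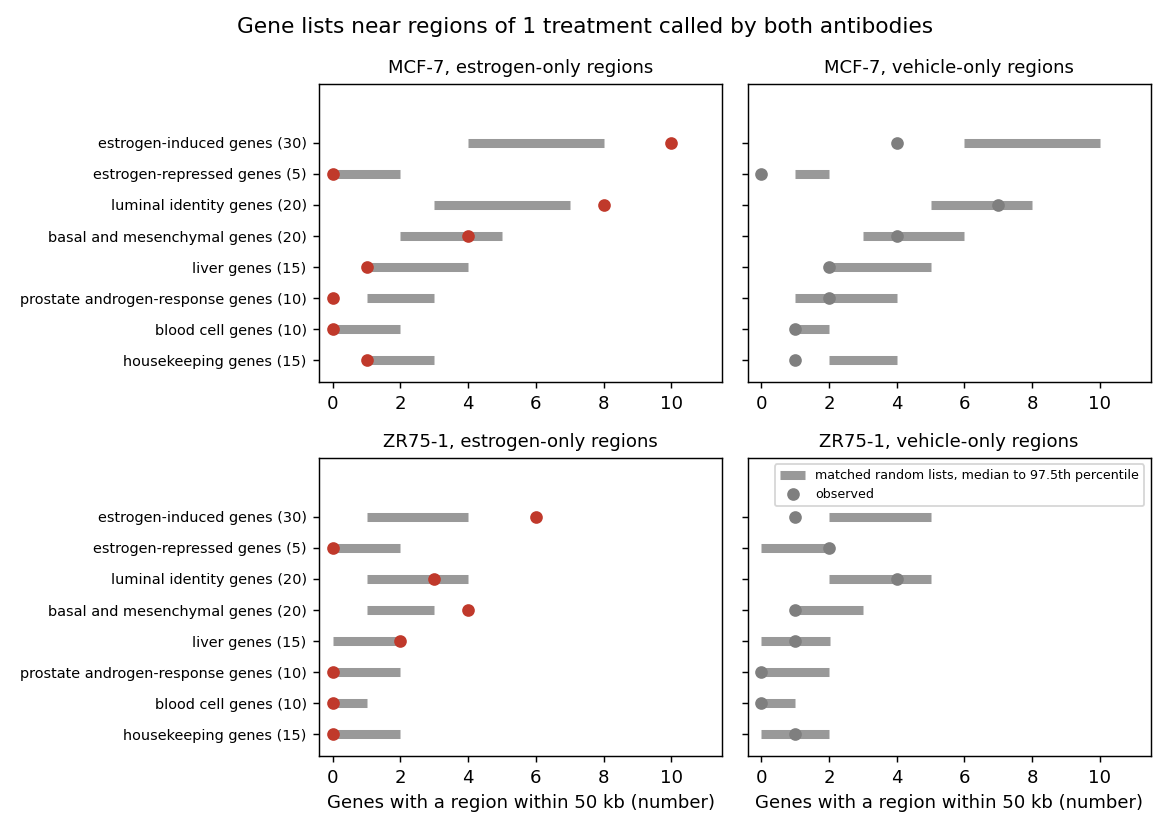
Number of genes (x axis) of each fixed list (y axis, list size in brackets) with an estrogen-only (red points) or vehicle-only (grey points) region of both antibodies within 50 kb, in MCF-7 and ZR75-1. Grey bars run from the median to the upper end of the central 95% of 10000 matched random lists; the estrogen-induced list lies at 10 in MCF-7 and 6 in ZR75-1, beyond the bars for estrogen-only regions.

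At individual estrogen target genes and regulators, 0 to 3 FOXA1 regions per gene and line were limited to 1 treatment with both antibodies. Within the GREB1 span (chromosome 2, 11482888 to 11642788), ZR75-1 had 2 estrogen-only regions of both antibodies (11498517 to 11498958 and 11502454 to 11502884). MCF-7 had 1 vehicle-only region (11597934 to 11598327), a weak one with fold enrichments of 2.56 and 2.37. A stronger ab5089 estrogen peak in MCF-7 (11498427 to 11499055, fold enrichment 11.4) had no ab5089 vehicle peak, but overlapped a vehicle peak of ab23738. TFF1, encoding a secreted trefoil peptide, had 16 regions in MCF-7, with 10 in all 4 lists and 1 estrogen-only, and 8 in ZR75-1, with 7 in all 4. PGR had 13 and 17 regions in MCF-7 and ZR75-1, with 3 and 2 in all 4 lists. Of the 17 in ZR75-1, 4 were in 1 estrogen list alone and 5 in 1 vehicle list alone. XBP1 had 13 and 22, with 10 and 9 in all 4 lists and 1 estrogen-only region in each line. CCND1, the cyclin D1 gene, had 5 and 7, with 1 in all 4 lists of either line. MYC had 16 regions in MCF-7, 1 of them estrogen-only, and 10 in ZR75-1. NRIP1, which encodes a nuclear receptor corepressor, had 33 and 16 regions, with 11 and 4 in all 4 lists. RARA, the retinoic acid receptor alpha gene, had 14 and 19, with 1 vehicle-only region in MCF-7. FOXA1 itself had 26 regions in each line, 12 and 11 in all 4 lists, with 1 vehicle-only region in each. ESR1 had 2 vehicle-only regions in ZR75-1. GATA3, a luminal transcription factor gene, had 14 and 8 regions and none limited to 1 treatment with both antibodies.

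**Figure D4:**
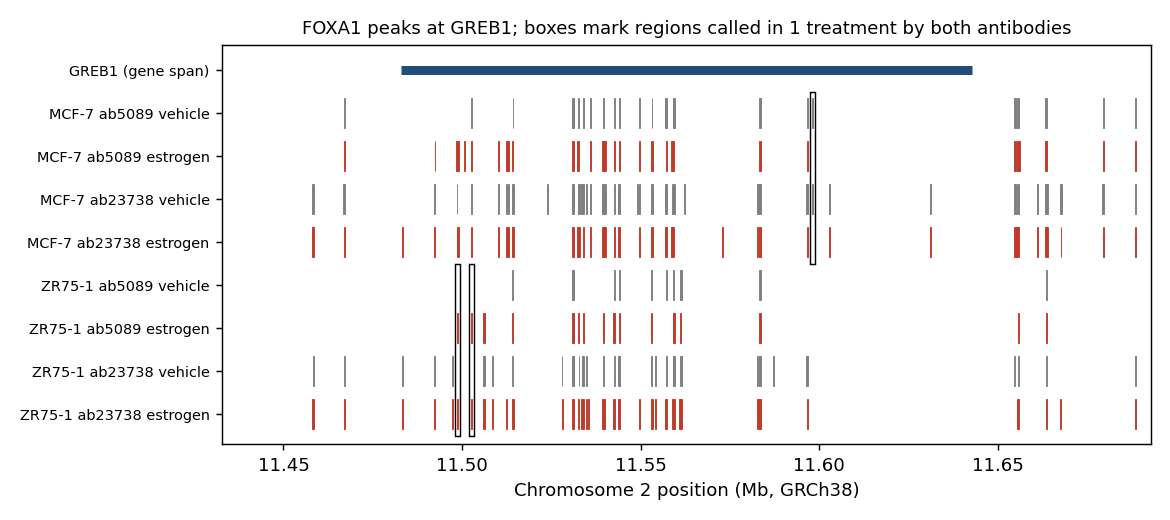
FOXA1 peaks of the 8 lists (rows) along chromosome 2 (x axis, Mb, GRCh38) at GREB1, from 50 kb before to 50 kb after the gene span (blue bar). Red marks are estrogen peaks and grey marks vehicle peaks; boxes mark the 2 estrogen-only regions of ZR75-1 and the 1 vehicle-only region of MCF-7 called by both antibodies.

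Nearly all ab5089 peaks were also ab23738 peaks, and not the reverse. Over the 4 comparisons together, 98.9% of ab5089 peaks overlapped an ab23738 peak, and the share was lowest in MCF-7 with estrogen (97.8%, interval 97.7 to 97.9). Of ab23738 peaks, 47.4% overlapped an ab5089 peak, from 41.4% in ZR75-1 with estrogen (41.2 to 41.7) to 51.9% in MCF-7 with estrogen (51.6 to 52.2). Limited to equal numbers of peaks, the shares were 85.3% and 84.0%. The ab23738 peaks without an ab5089 peak were the weaker ones. In MCF-7 vehicle they had a median of 37 reads at the summit against 79 for those with one, and in ZR75-1 estrogen 45 against 114. None of the strongest 10% of ab23738 peaks in MCF-7 lacked an ab5089 peak in either treatment, against 91.4% of the weakest 10% with vehicle.

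The cell lines differed more than the treatments. Of MCF-7 peaks, 57.5% overlapped a ZR75-1 peak of the same antibody and treatment, from 51.1% (50.7 to 51.5) with ab5089 and estrogen to 61.7% (61.4 to 61.9) with ab23738 and estrogen. Of ZR75-1 peaks, 61.6% overlapped a MCF-7 peak. All 8 lists merged into 201751 regions, of which 27826 were called in every list. There were 7071 MCF-7-specific regions, called in all 4 lists of MCF-7 and none of ZR75-1, and 7868 ZR75-1-specific regions. These were 13.8% and 17.5% of the regions called in all 4 lists of the line. The split varied by chromosome. Chromosome 6 had 744 MCF-7-specific and 241 ZR75-1-specific regions, and chromosome 18 had 75 and 424.

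Line-specific regions included some of the strongest peaks. The MCF-7-specific region with the highest mean rank lay between genes on chromosome 19 (31555380 to 31556434), 204503 bp from TSHZ3, with fold enrichments of 33.6 to 37.5 in the 4 lists of the line. It was followed by regions within GABBR2 and CPPED1 and by regions in or nearest to UTRN, TMEM161B, ATXN1, DOCK5, DLG2, PRP4K and POLQ. In ZR75-1 the leading region lay on chromosome 4 (116676627 to 116677773), 405781 bp from TRAM1L1, with fold enrichments of 29.1 to 35.8. The next lay within MTAP (chromosome 9, 21863287 to 21864314; 28.9 to 38.2) and within GRXCR1, followed by regions in or nearest to GPC5, ZNF326, UNC5D, ASIC2, ADCY2, DOK6 and STAM2. Copy number was not measured at any of these regions. The lists therefore cannot tell absent binding in the other line from DNA that this line lacks. ESR1 had 6 MCF-7-specific regions within 50 kb and 1 ZR75-1-specific region, and TFF1 had 3 MCF-7-specific regions. The chromosomes of these genes leaned the same way. MCF-7-specific and ZR75-1-specific regions numbered 744 and 241 on chromosome 6 (ESR1), and 125 and 71 on chromosome 21 (TFF1). No gene list lay above the central 95% of matched random lists for line-specific regions. The highest was the luminal list, with 12 of 20 genes near MCF-7-specific regions (84.8%) and 10 of 20 near ZR75-1-specific regions (84.8%).

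**Figure D5:**
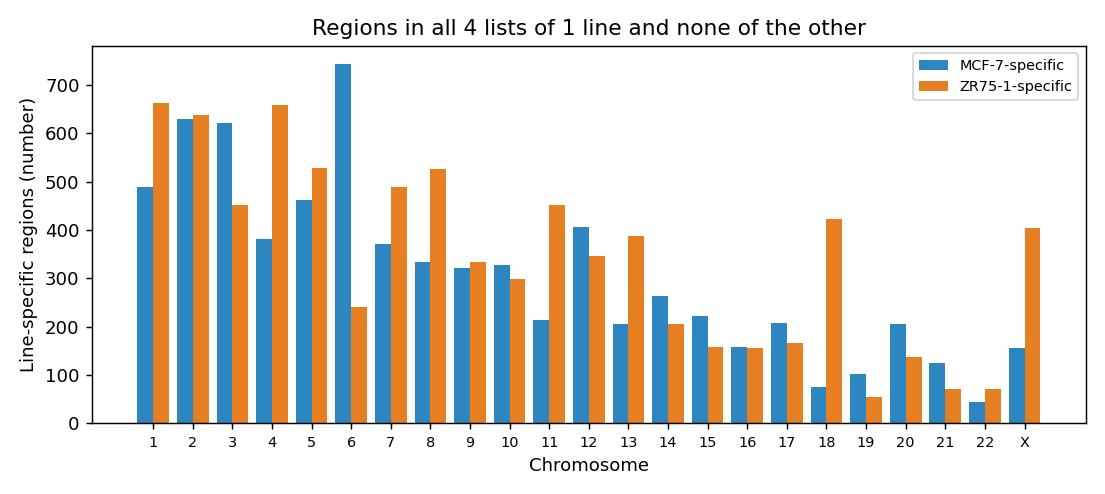
Number of regions (y axis) called in all 4 lists of 1 line and in none of the other, by chromosome (x axis; blue, MCF-7-specific; orange, ZR75-1-specific). Chromosome 6 has 744 MCF-7-specific against 241 ZR75-1-specific regions and chromosome 18 has 75 against 424.

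Of the 10 strongest regions shared by all 8 lists, 3 lay within a gene span. The region with the highest mean rank was on chromosome 10 (107748927 to 107750352), 567789 bp from SORCS1, with fold enrichments of 32.4 to 41.4 in the 8 lists. The others were nearest to CRIM1, IDO1, FBXO4, CAMK1D, AKAP6, BHMT, HABP2, EYS and ATRNL1. The regions of CAMK1D, AKAP6 and ATRNL1 were those within the gene span.

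FOXA1 summits were mostly away from the ends of protein-coding genes. Of all summits, 4.51% lay within 1 kb of either end of a gene span (4.46 to 4.56), from 3.76% in ZR75-1 ab5089 estrogen to 5.10% in ZR75-1 ab23738 vehicle. Between 45.6% and 49.6% of summits lay within a gene span. The shares of the genome near gene ends or within gene spans were not measured, so neither enrichment nor depletion was assessed. Estrogen-only regions of both antibodies had 3.30% near a gene end in MCF-7 (2.51 to 4.34) and 3.35% in ZR75-1 (2.10 to 5.29), and regions called in all 4 lists had 4.27% (4.10 to 4.45) and 3.74% (3.57 to 3.92). The intervals overlapped in both lines at this distance. Within 5 kb the order in ZR75-1 turned and the intervals did not overlap, with 15.4% of estrogen-only regions (12.5 to 18.7) against 11.7% of regions in all 4 lists (11.4 to 12.0), whereas MCF-7 had 11.7% against 13.3%, with overlapping intervals.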

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

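The comparison of recovered reads between treatments, its tests (scaling, both lines, estrogen-induced genes) and the test of depth between the antibodies were chosen after the results were seen, and the test of enrichment per read was written before its result. Reads at the summits, solved from the deposited values and not otherwise compared, differed between treatments at some regions called in all 4 lists of a line. In MCF-7, 296 of 48835 regions were at least 1.5-fold higher with estrogen with both antibodies and 51 were lower, where 19.1 and 8.58 would be expected of independent antibodies. In ZR75-1, 259 of 42909 regions were higher and 41 lower (14.6 and 4.82 expected). Simulations of unchanged regions gave means of 16.8 higher and 19.1 lower in MCF-7 and 5.82 and 5.68 in ZR75-1, but cover counting error only and not the spread between ChIP preparations. Most regions moved little: 93.4% in MCF-7 and 94.3% in ZR75-1 stayed within 1.5-fold with both antibodies. The difference between treatments has 1 list per condition behind it, so no replicate check, and the reads were not scaled by the input.

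Of the excess of higher over lower regions, technical and biological explanations were weighed. Scaling stays open in both lines: scaling by background reads differed from the main scaling in MCF-7 by only −0.03 and 0.02 log2, too little to test it (6.13 higher regions per lower region), and in ZR75-1 by −0.05 and −0.17 log2, with 0.643 (126 higher and 196 lower) but 7 higher and 1 lower past 2-fold. For culture differences within a line, 24866 regions with 1 peak in each of the 8 lists were compared, of which 114 were higher in MCF-7 and 113 in ZR75-1. Of these, 41 were higher in both lines, 79.1 times the 0.518 expected of independent lines (28 with background scaling, where 0.281 were expected). The expected numbers treat all regions as equally likely to change and were not matched on strength. The excess over them therefore does not exclude culture differences. Action of the estrogen receptor near estrogen-induced genes remains a hypothesis, with handling common to both lines untested: 9 of 30 such genes in MCF-7 and 7 of 30 in ZR75-1 had a higher region within 50 kb, more than in 100% of 10000 random lists in either line, and with background scaling 9 and 3 (mean of random lists 1.23 and 0.417; above 100% and 99.3% of them).

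The ab23738 lists held 1.86 to 2.37 times as many peaks as the ab5089 lists. Deeper ab23738 libraries were argued against, since background reads were at most 1.23 times those of ab5089 and were lower in 2 of the 4 pairs. Weaker enrichment per read with ab5089 may account for it: at 24866 regions with 1 peak in each of the 8 lists, reads over background were higher with ab23738 by a median ratio of at least 1.31 in each of the 4 pairs. Why enrichment differed was not tested, and no biological explanation was tested.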

How the results depend on the processing

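The alternatives for recovered reads, unlike the others, are tests chosen after the results were seen. No paired analysis was possible because the lists carry no replicate, although the labels number replicates 1 to 3 in every group. For the same reason no replicate could be left out. The 3 motif alternatives were not run. With summits within 100 bp, pooled shares of estrogen and vehicle peaks with a peak of the other treatment were 80.6% and 74.8%, shares of ab5089 and ab23738 peaks with one of the other antibody 93.9% and 45.6%, and shares of MCF-7 and ZR75-1 peaks with one of the other line 54.1% and 57.9%. With 50% overlap of both peaks they were, in the same order, 81.2%, 75.4%, 90.7%, 44.0%, 50.2% and 53.7%. With equal numbers of peaks they were 81.7%, 81.6%, 85.3%, 84.0%, 59.6% and 59.8%. By construction these alternatives ask more of an overlap or drop the weaker peaks of the longer list. A −log10 q of 5, which 94.0% to 96.7% of the peaks of a list passed, moved the ab23738 share to 47.8%, the MCF-7 share to 57.9% and the ZR75-1 share to 61.0%. The cause was not tested. Strong estrogen peaks without a vehicle peak were 0.0393% among the strongest 5%. With equal numbers, estrogen-only regions of both antibodies numbered 3042 in MCF-7 and 2197 in ZR75-1, and vehicle-only regions 2111 in ZR75-1. Shorter ab23738 lists leave more regions uncalled by construction. Within 5 kb of a gene end lay 13.4% of summits. Scaling by background reads gave 126 higher and 196 lower regions in ZR75-1, or 39.1% higher against 86.3%, and its cause was not tested. Past 2-fold, higher and lower regions numbered 27 and 0 in MCF-7 and 21 and 0 in ZR75-1, and with background scaling 29 and 0, and 7 and 1. The other 35 alternative values of these results stayed within their interval or within 1.5 times the count. Of the single comparisons and gene lists, 150 values were counted as moved and 69 were not. Those counted as moved include gene-list counts that were 0 in both settings, so the number overstates the change. Peaks near the calling threshold limit all counts of regions called in 1 treatment.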

Other observations

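The genes named here for their reads were chosen after their values were seen, as were all tests of reads between treatments. The tests of enrichment per read and of copy number were written before their results. Of 30 estrogen-induced genes, 9 in MCF-7 and 7 in ZR75-1 had a region within 50 kb that was higher with estrogen with both antibodies, or 9 and 3 (TFF1, CA12 and CCN5, not CTSD) when scaled by background reads; most of the 296 and 259 higher regions were not near genes of this list. Near CTSD, the cathepsin D gene, reads at chromosome 11, 1796289 to 1797131 (GRCh38) were 50 with vehicle and 212 with estrogen in MCF-7 with ab5089 and 58 and 82 with ab23738, and in ZR75-1 71 and 183 and 127 and 198. At a region within TMPRSS3 and less than 50 kb from TFF1 in ZR75-1 (chromosome 21, 42376075 to 42376782) they were 67 and 189 with ab5089 and 133 and 269 with ab23738. SIAH2, an estrogen-induced ubiquitin ligase gene, had 60 and 267 and 104 and 167 in MCF-7 (chromosome 3, 150736993 to 150737851). Within GREB1 in MCF-7 (chromosome 2, 11532182 to 11533013) reads were 38 and 119 with ab5089 and 42 and 75 with ab23738. Outside the list, regions higher in both lines lay within ITPK1 (chromosome 14, 93016962 to 93017848; log2 ratios 2.49 and 0.86 in MCF-7 and 1.63 and 0.91 in ZR75-1), IGF1R and ERBB4. At CASP7 in ZR75-1, ab5089 reads were 34 with vehicle and 194 with estrogen. All of these regions had peaks in both treatments.

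With the median of each list set to 0, log2 ratios at regions higher in the other line were larger with ab5089 than with ab23738. At regions chosen as higher in ZR75-1, ab5089 changed more in MCF-7 at 93.8%, with medians of 1.06 and 0.45. At regions chosen as higher in MCF-7, ab5089 changed more in ZR75-1 at 75.4%, with medians of 0.73 and 0.47. Over all regions, too, log2 ratios were more spread with ab5089 than with ab23738 (SD 0.30 and 0.24 in MCF-7, 0.29 and 0.22 in ZR75-1).

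Line-specific regions were spread unevenly over chromosomes, for example 75 in MCF-7 and 424 in ZR75-1 on chromosome 18, 744 and 241 on chromosome 6, and 156 and 404 on chromosome X. Copy number may contribute: over 23 chromosomes, the log2 ratio of MCF-7-specific to ZR75-1-specific regions rose with the log2 ratio of local background at shared regions (Pearson r 0.703, two-sided permutation p = 0.00026; Spearman rho 0.677, p = 0.00069). Without chromosomes 18 and 21, r was 0.542 (permutation p = 0.011), and over 281 bins of 10 Mb it was 0.672 (p = 1e-05, the smallest these permutations give), although bins are not independent. Local background is a stand-in for copy number, which was not measured, and regulation that differs between the lines stays open and untested.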
